A study of Mus musculus with 23 samples.

How the data were processed

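The samples were 23 pools of mouse nucleus accumbens tissue, each hybridised as biotin-labelled cRNA to 1 Affymetrix expression array. Group, dose, mean age and chip lot were taken from the labels. The deposited table gives 1 value per probe set and array. Its log2 scale was inferred from the values, since the labels do not state it: they run from 2.23 to 16.4. The authors had normalized the deposited log2 values between arrays, as their nearly coinciding sorted values show; the method, the background correction and the probe set summary are not given in the sources used here. R 2.7.1 is named in the submitters' processing notes, without its role.

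The lowest value recurs across probe sets and made up 33.0% of all values. Values under 2.3 were treated as the floor, and 2089 genes (25.3%) lay at the floor on every array. Signal over this floor, not a count of reads, sets what the arrays can measure. Of 12488 probe sets, 66 are controls, 10833 were listed with 1 gene, 396 with several genes and 1193 were not listed; these last kinds were not named. Of the 10833, 10817 matched the RefSeq table of the GRCm38.p6 assembly by gene identifier and took its current symbols. For 2073 genes with several probe sets, the one with the highest mean was used, giving 8251 genes. No coordinates are printed, because the files name no genome build.

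The labels describe 4-way pools but not how animals were shared among them, so p-values measure the spread between these pools. All 253 pairs of arrays differed, with a smallest mean absolute difference of 0.131, so no array was counted as a copy of another. Replicate numbers are shared between groups in the labels. Within a line, same-numbered pools had similar mean ages and, with the fourth lot counted with the third, the same chip lot, but the labels do not say that a number marks a batch. A block on the numbers is an alternative only, so p-values of the model take the arrays as independent. Same-numbered pools varied together in part, so p-values of the line differences may be too small.

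Comparisons used limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes in 1 fit of 4 group means over all 23 arrays and no covariates. The Benjamini-Hochberg adjusted p-value was set under 0.05 over 8251 genes, and all tests were two-sided. There were 7 comparisons. Differences are on the log2 scale with standard errors from the moderated fit. On simulated data with the real means and residual spreads, independent normal noise and 100 changed genes of each size, changes of 1 log2 unit were recovered in 58% of cases for the effect in HMACT, 70% for the mean effect of methamphetamine and 74% for the mean line difference, over 8251 genes. Changes of 0.5 log2 units were recovered in 22%, 47% and 46%, and no called gene had the wrong sign. Among unchanged genes, 2, 6 and 5 were called. In the data the noise is shared between genes and far fewer genes were called, and many changed genes loosen the adjusted threshold. The simulation therefore does not give the recovery or error rate in the data.

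The 19 gene lists, with 365 different genes, were written before the data were examined, and 17 had 3 or more members on the array. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 119 tests, with an estimated correlation and fry as alternatives. The named genes were set by a rule written before the data were examined: among genes past the threshold, the 10 smallest p-values in each direction for the 2 mean comparisons and 3 in each direction for the other comparisons of groups. For the interaction it was the 3 smallest p-values if none passed. From each list it took up to 4 members past the threshold in the mean comparisons or otherwise up to 2, and Csnk1e throughout. That list members count as past when adjusted over the list alone was settled after the fit was seen. Not all list members are named in the text.

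Alternatives set before the data were examined were quantile normalization, median centring, leaving out the dimmest 40% of genes, other uses of probe sets, eBayes with trend and robust, array weights, chip lot, mean age, blocks on replicate number, fits of only the groups compared, and leaving out each array. Others were chosen after seeing the data: leaving out genes at the floor, leaving out the 4 arrays that stand apart, and the array axis as a covariate. The axis is the first principal component of residuals from group means over 5308 genes above the floor on most arrays. The rule for arrays that stand apart, a score over the median plus 3.5 median absolute deviations, was also set after the scores were seen. The sample columns of the table were all used. GC content and probe sequences were not analysed here.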

Results

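Messenger RNA levels were measured in the nucleus accumbens, a ventral striatal region that receives dense dopamine input, of mice from selected lines. The lines were bred from a C57BL/6J x DBA/2J stock for a high (HMACT) or low (LMACT) acute response to methamphetamine, a psychostimulant that releases dopamine. Mice of each line received saline or 2 mg/kg methamphetamine, and tissue was taken 1 hour later. Each of the 23 arrays measured a 4-way tissue pool: 6 of HMACT after saline, 6 of HMACT after methamphetamine, 6 of LMACT after saline and 5 of LMACT after methamphetamine. The table held 12488 probe sets, and 8251 genes were tested. The number of arrays limits the precision of every value below.

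The HMACT pools were older. Their mean age was 114.65 ± 34.9 days (SD, n = 12), against 76.6 ± 22.5 days (SD, n = 11) for LMACT. The HMACT ages were not spread evenly: replicates 1 to 3 were 141.5 to 154 days and replicates 4 to 6 were 77.25 to 88 days. In LMACT, replicate 6 was 127.5 days after saline and 114.75 days after methamphetamine, and the others were 60 to 72.75 days. The labels named 4 chip lots, and all groups were represented in the lot of 15 arrays. Within groups, 62.1% of the residual variance over 5308 genes lay along a single axis. On that axis 4 arrays stood apart, with scores from 41.8 to 65.0 against -22.8 to 23.8 for the other 19. They were HMACT saline replicates 3 and 5, HMACT methamphetamine replicate 3 and LMACT methamphetamine replicate 4. On these arrays Gnai3, a G protein subunit gene, was lower by a log2 difference of -4.96, and the complement gene C1qa was higher by 2.58.

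**Figure D1:**
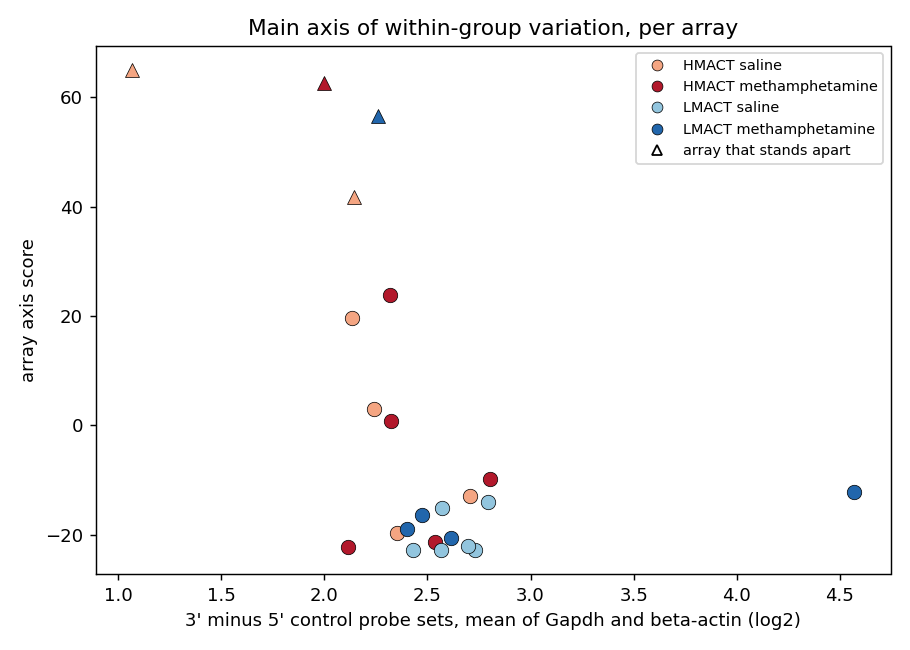
Each point is 1 of the 23 arrays, coloured by group, with the 3' minus 5' difference of the control probe sets (log2, mean of Gapdh and beta-actin) on the x axis and the array axis score on the y axis. The 4 arrays that stand apart (triangles) score from 41.8 to 65.0, and their 3' minus 5' differences range from 1.07 to 2.26.

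The first question was which genes differed 1 hour after methamphetamine as a mean of both lines. Immediate early genes, which neurons transcribe within minutes of stimulation, rose as a group, and a pair of genes passed the test over all genes. Btg2, an antiproliferative early response gene, rose by a log2 difference of 0.88 (SE 0.0929), which is 1.84-fold. Hspa1b, which encodes an inducible HSP70 chaperone, fell by 1.71 on the log2 scale (SE 0.259), which is 3.26-fold. Both moved in the same direction in all 11 methamphetamine arrays, each set against the saline mean of its own line. Btg2 averaged 8.66 ± 0.40 (SD, n = 6) after saline and 9.62 ± 0.08 (SD, n = 6) after methamphetamine in HMACT. In LMACT it averaged 8.98 ± 0.10 (SD, n = 6) and 9.79 ± 0.15 (SD, n = 5). Hspa1b averaged 6.18 ± 0.71 and 4.45 ± 0.47 in HMACT (SD, n = 6 each).

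Of the 34 immediate early genes on the array, 1 passed over all genes and 7 passed when adjusted over the list alone, all of them higher; 27 did not pass. After Btg2, the smallest p-values belonged to the transcription factor genes Atf3, Klf4 and Egr2. Their log2 differences were 0.95 (SE 0.185), 0.79 (SE 0.165) and 0.56 (SE 0.122). The others were Dusp1, Fos and Ccn1; Fos (log2 difference 0.67, SE 0.180) and Ccn1 (0.42, SE 0.138) were named after their values were seen. Among 33 members not at the floor on every array, 25 had a positive difference and the median was 0.15. The competitive list test gave an adjusted p of 2.7e-17, and the call held with an estimated correlation (adjusted p = 0.0012).

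Glucocorticoid responsive genes were higher after methamphetamine as a list. Of 25 measured members, 0 passed over all genes and 5 when adjusted over the list alone, all higher. Txnip, an inhibitor of thioredoxin, had a log2 difference of 0.93 (SE 0.241) and Dusp1, a MAP kinase phosphatase, 0.80 (SE 0.207). For Cebpd, a transcription factor, it was 1.31 (SE 0.401), and for Ddit4, an inhibitor of mTOR signalling, 0.77 (SE 0.249). Cdkn1a, the cell cycle inhibitor p21, was named after its value was seen (1.00, SE 0.330). Dusp1 is also a member of the immediate early list. The list's adjusted p was 4.8e-05, and the call was lost with an estimated correlation (adjusted p = 0.079).

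Heat shock and oxidative stress genes were called lower as a list by the competitive test. Of 24 measured members, 1 passed over all genes and 3 when adjusted over the list alone, all of them chaperone genes and all lower. These were Hspa1b, its near-identical neighbour Hspa1a with a log2 difference of -1.01 (SE 0.205), and the HSP40 co-chaperone gene Dnajb1 with -0.59 (SE 0.178). Probes for Hspa1a and Hspa1b may detect both transcripts, so the values of the pair are uncertain as separate measurements. Of 22 members not at the floor on every array, 14 had a negative and 8 a positive difference, and the median was -0.07. The values therefore do not show a fall across the whole list. The list's adjusted p was 0.0019. The call was lost with an estimated correlation (adjusted p = 0.134) and with fry (adjusted p = 0.333).

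**Figure D2:**
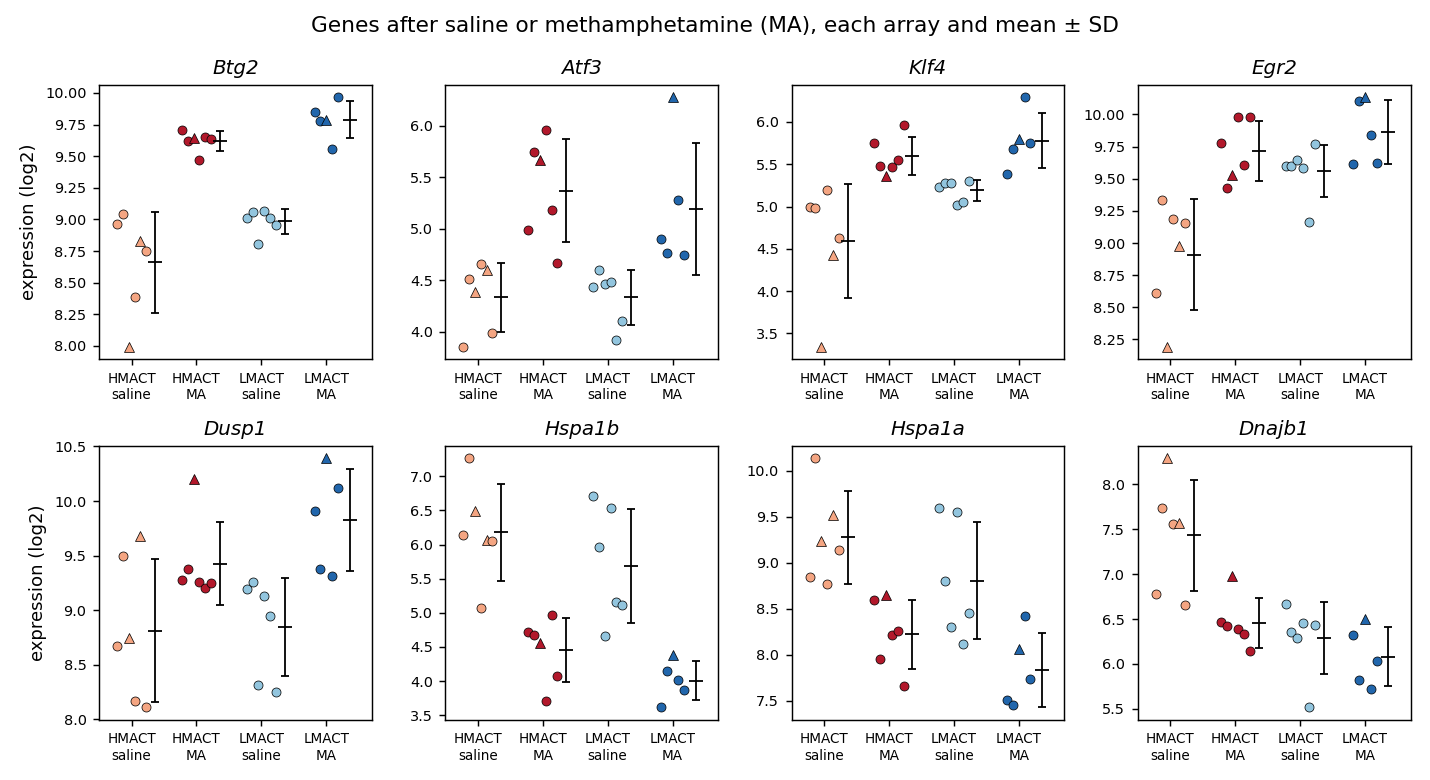
Expression (log2) of 8 genes on each array, by line and injection; points are arrays, triangles the 4 arrays that stand apart, and the black marks give mean ± SD of a group. Btg2 lies higher and Hspa1b lower in all 11 methamphetamine arrays than the saline mean of the same line.

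Mitochondrial respiratory chain genes were lower as a list by small amounts. No member of 33 passed when adjusted over the list alone, 27 of the 32 above the floor had a negative difference, and the median was -0.06. Cox7a2 had the smallest p, with a log2 difference of -0.45 (SE 0.143), followed by Ndufv2 with -0.29 (SE 0.141), which was -0.17 without HMACT saline replicate 3. The list's adjusted p was 6.1e-04, and the call was lost with an estimated correlation (adjusted p = 0.342) and without the 4 arrays that stand apart (adjusted p = 0.0851).

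The remaining lists did not pass in this comparison. Striatal projection neuron genes (adjusted p = 0.977; Arpp19 -0.65, SE 0.528; Drd2 0.20, SE 0.210), glutamate and GABA synapse genes (adjusted p = 0.955; Grik1 0.12, SE 0.0530; Slc32a1 0.25, SE 0.152) and monoamine genes (adjusted p = 0.823; Slc6a4 0.09, SE 0.0524; Slc6a2 -0.04, SE 0.0368) gave no call. With array weights the direction of Arpp19 turned (0.24), and Drd2 was near 0. These values rest on few arrays: without LMACT methamphetamine replicate 4, which stands apart, Arpp19 was -0.31, Drd2 0.08 and Cry2 0.01. Grik1 was 0.07 without LMACT methamphetamine replicate 6, Slc6a4 0.06 without HMACT saline replicate 1 and Slc6a2 -0.01 without LMACT saline replicate 4. Circadian clock genes had an adjusted p of 0.955, and their smallest p-values were those of Cry2 (0.04, SE 0.0288), which was at the floor on 21 arrays, and Csnk1e. Csnk1e, which encodes casein kinase 1 epsilon and was chosen in advance for every comparison, had a log2 difference of -0.22 (SE 0.188), and -0.07 without LMACT methamphetamine replicate 5.

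With limma, 1 gene passed higher and 1 lower at an adjusted p under 0.05, with adjusted p-values of 8.1e-05 for Btg2 and 0.0099 for Hspa1b. At an unadjusted p under 0.05 there were 124 genes, and chance would give 412.55 if all 8251 genes were independent. The genes vary together, and 2089 of them lay at the floor on every array, so the lower count was given no meaning. In the lot of 15 arrays alone 0 genes passed, and the log2 differences there were 0.89 for Btg2 and -1.69 for Hspa1b. Among the 4 arrays that stand apart, leaving out HMACT saline replicate 3 gave 5 genes, and leaving out all 4 gave 5, with Hspa1b at an adjusted p of 0.067.

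In HMACT alone, Btg2 rose by a log2 difference of 0.96 (SE 0.128), and it was the only gene past the threshold over all genes. The immediate early list rose, with 5 members past when adjusted over the list alone: Btg2, Klf4 (log2 difference 1.00, SE 0.227), Atf3 (1.04, SE 0.256), Egr2 (0.81, SE 0.169) and Fos (0.93, SE 0.249). The list's adjusted p was 1.6e-08, and 0.030 with an estimated correlation, but the call was lost with fry (adjusted p = 0.095). The glucocorticoid responsive list was higher at an adjusted p of 0.0030, with 0 members past when adjusted over the list alone, and its call was lost with an estimated correlation (adjusted p = 0.221) and without HMACT methamphetamine replicate 2 or 3. The heat shock and oxidative stress list was not called (adjusted p = 0.477, 11 of 22 members positive), although Hspa1b (-1.73, SE 0.358), Hspa1a (-1.05, SE 0.282) and Dnajb1 (-0.98, SE 0.246) passed when adjusted over the list alone. The mitochondrial respiratory chain list was not called (adjusted p = 0.477, 25 of 32 members negative). Each of these non-calls rests on 1 array: the heat shock list passed without HMACT saline replicate 3, which stands apart, and the mitochondrial list without HMACT saline replicate 1. The oligodendrocyte markers passed in HMACT without the 4 arrays that stand apart and without HMACT methamphetamine replicate 2. Csnk1e had a log2 difference of -0.26 (SE 0.259), and -0.41 without HMACT saline replicate 4 or -0.12 without HMACT saline replicate 3. The adjusted p of Btg2 was 0.0032 in the fit of all 23 arrays, and 128 genes had an unadjusted p under 0.05. A fit of the 12 HMACT arrays alone and a block on replicate number each called 0 genes, and leaving out HMACT saline replicate 6 called 2.

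In LMACT alone no gene passed over all genes. The smallest p was again that of Btg2, with a log2 difference of 0.80 (SE 0.134) and an adjusted p of 0.070. The immediate early list rose (adjusted p = 2.4e-07, and 0.043 with an estimated correlation), with Btg2 the single member past when adjusted over the list alone. Its call was lost with fry (adjusted p = 0.064). The heat shock and oxidative stress list was lower at an adjusted p of 0.0070, with Hspa1b (-1.69, SE 0.375) and Hspa1a (-0.97, SE 0.296) past when adjusted over the list alone; the call was lost with an estimated correlation (adjusted p = 0.216) and without LMACT methamphetamine replicate 2 or 3. The mitochondrial respiratory chain list was lower at an adjusted p of 0.0051, with 22 of 32 members negative, and its call was lost too (adjusted p = 0.608 with an estimated correlation), as it was without LMACT methamphetamine replicate 3. The glucocorticoid responsive list was not called (adjusted p = 0.0656, 15 of 20 members positive). It passed without genes at the floor, with the mean of all probe sets of a gene, and without any 1 of 4 arrays: HMACT methamphetamine replicate 2, LMACT saline replicates 2 and 3, and LMACT methamphetamine replicate 2. Csnk1e had a log2 difference of -0.17 (SE 0.272); without LMACT methamphetamine replicate 5 its direction turned (0.11), and without replicate 4 of that group it was -0.29. With limma, 0 genes passed and 275 had an unadjusted p under 0.05. Array weights gave 25 genes, and leaving out HMACT saline replicate 2 or 3 gave 1 and 2.

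The interaction asked whether the difference after methamphetamine was not the same in the lines. With limma no gene passed, and 216 genes had an unadjusted p under 0.05. Independent genes would give 412.55 by chance, but these vary together, so this lower count was given no meaning either. The smallest p-values were those of Cramp1l, a chromatin regulator gene (HMACT minus LMACT effect -0.59, SE 0.175), the transcription factor gene Klf3 (-0.45, SE 0.136) and Nudt3, a Nudix hydrolase gene (-0.92, SE 0.283), all at an adjusted p of 0.860. The interaction of Btg2 was 0.16 (SE 0.186) and that of Hspa1b -0.04 (SE 0.519). Dnajb1, whose log2 difference was -0.98 (SE 0.246) in HMACT and -0.21 (SE 0.258) in LMACT, had an interaction of -0.77 (SE 0.356) at an adjusted p of 0.860. Csnk1e had -0.09 (SE 0.376), and its direction rests on single arrays: it was -0.38 without LMACT methamphetamine replicate 5 and 0.06 without HMACT saline replicate 3. None of the 17 lists tested passed; the smallest adjusted p was that of the choroid plexus and ependymal markers, 0.477. Without the 4 arrays that stand apart, the mitochondrial respiratory chain list was called.

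Across all 8251 genes, which are not independent replicates, the methamphetamine effects in HMACT and LMACT had a Pearson r of -0.427 and a Spearman rho of -0.356. When injection labels were permuted within lines, 71 of 100 permutations gave a Pearson r at or above the real one, over a range of -0.815 to 0.807. How many lay as far from 0 in either direction was not counted. The comparisons share no array. With the array axis as a covariate, an alternative chosen after seeing the data, r was 0.0837. At an unadjusted p under 0.05, 6 genes were higher in both lines, against 0.929 expected from independent lists, and 2 were lower in both, against 0.928. The lists are not independent, since both comparisons use the same estimate of a gene's spread. The expectation also counts genes at the floor, so it may be too low. These counts were not permuted, so they do not show a shared response.

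**Figure D3:**
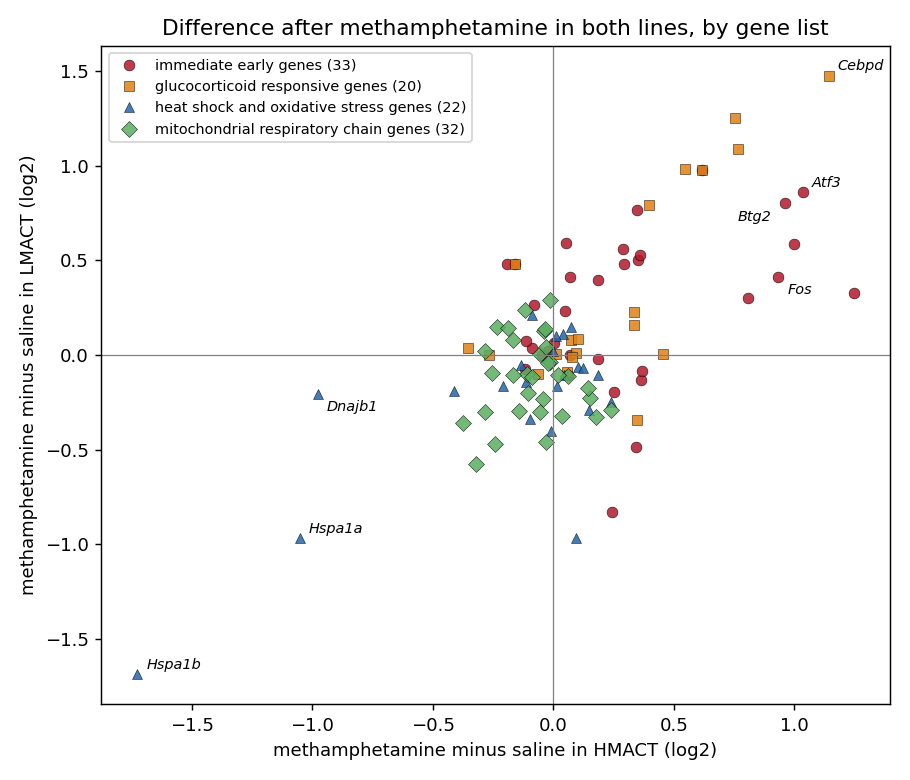
Log2 difference after methamphetamine in HMACT (x axis) and LMACT (y axis) of each member of 4 gene lists that was above the floor on at least 1 array. Btg2 (0.96 and 0.80) and Hspa1b (-1.73 and -1.69) lie on the same side of 0 in both lines.

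The second question was which genes differ between the selected lines, as a mean over both injections. Of 16 genes past the threshold, 11 were higher and 5 lower in HMACT. Nudt19, a peroxisomal Nudix hydrolase gene that acts on coenzyme A, was lower by a log2 difference of -2.07 (SE 0.294), which is 4.19-fold. Its means were 7.06 ± 1.22 and 6.88 ± 0.45 in HMACT after saline and methamphetamine (SD, n = 6 each). In LMACT they were 8.95 ± 0.33 (SD, n = 6) and 9.12 ± 0.38 (SD, n = 5). The others lower in HMACT were Prom1, the membrane glycoprotein prominin (-0.85, SE 0.152), Med1, a Mediator subunit (-0.66, SE 0.123), the sorting nexin gene Snx14 (-0.50, SE 0.0948) and the glycosyltransferase gene Galnt11 (-0.42, SE 0.0733).

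The genes higher in HMACT had several functions. Slc15a2, a peptide transporter gene, was higher by 1.14 (SE 0.170), or 2.21-fold. Psmb6, a proteasome subunit gene, was higher by 1.57 (SE 0.292). Pih1d1, a co-chaperone gene, was higher by 1.51 (SE 0.241), Pttg1, the securin gene, by 1.51 (SE 0.265) and Coa3, a cytochrome c oxidase assembly gene, by 1.44 (SE 0.241). Coro2b was higher by 1.06 (SE 0.213) and Cfl1, which encodes the actin-severing protein cofilin, by 0.89 (SE 0.165). The membrane glycoprotein gene Cd200 was higher by 0.73 (SE 0.120), Dkk3 by 0.69 (SE 0.131) and Blcap by 0.53 (SE 0.0878). Nfu1, an iron-sulphur cluster gene outside the naming rule, was named after its value was seen (0.50, SE 0.103). Blcap overlaps Nnat, so the signals of this pair may not be separate. Of the 16 genes, 1 (Prom1) had a second probe set above the floor, and it differed in the same direction by -0.46 (SE 0.0882); the second probe sets of Coro2b and Pttg1 were at the floor.

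**Figure D4:**
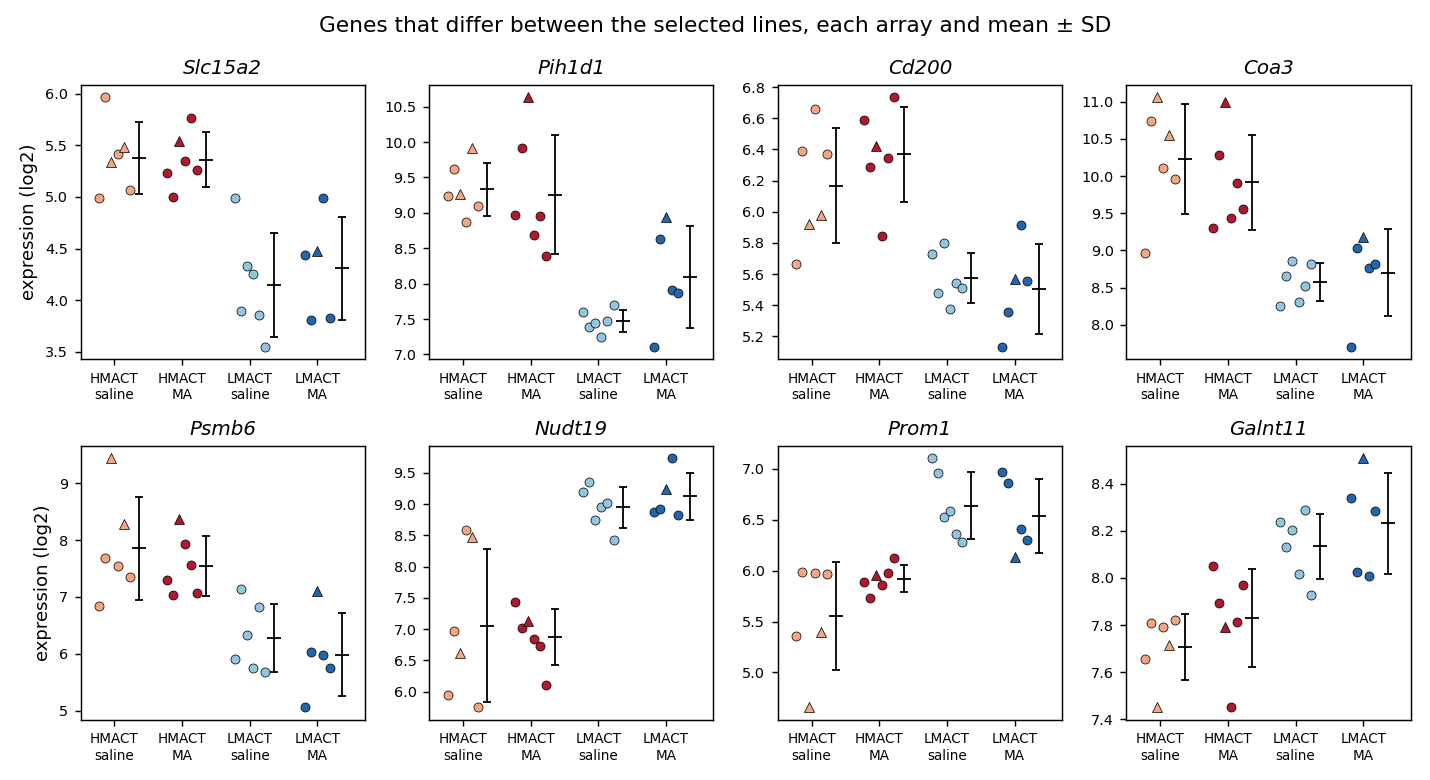
Expression (log2) of 8 of the genes that differ between the lines on each array, by line and injection; points are arrays, triangles the 4 arrays that stand apart, and the black marks give mean ± SD of a group. For each gene shown, all 12 HMACT arrays lie on 1 side of the LMACT mean after the same injection.

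With limma the adjusted p-values of the 16 genes ran from 0.0077 for Nudt19 and Slc15a2 to 0.047 for Nfu1, and 1045 genes had an unadjusted p under 0.05. All 15 genes named by the rule kept their direction in all 3 lots, with the single array of the fourth lot counted with the third. The lots are parts of the arrays on which these genes were chosen, so this is not independent support. The mean 3' minus 5' control difference after saline and methamphetamine was 2.11 and 2.35 in HMACT. In LMACT it was 2.63 and 2.87, the latter with replicate 5 at 4.57. RNA integrity was not tested for these genes. The pools of the lines also differed in age. With mean age as a covariate 1 of the 16 genes was called. In the 15 pools under 100 days alone 0 of the 16 were called, and the 1 gene that passed there was another; all 16 kept their direction in both. Counts also moved with the arrays: 76 genes passed without LMACT methamphetamine replicate 4, 9 without LMACT methamphetamine replicate 6, 10 without LMACT saline replicate 6, 46 without the 4 arrays that stand apart, and 677 with array weights. A random block of line and number, which lets same-numbered pools vary together, kept 4 of the 16 calls.

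No gene list passed in the mean difference between lines. The oligodendrocyte markers came nearest (adjusted p = 0.0656). They passed with mean age as a covariate, and so did the immediate early genes. They also passed with the array axis as a covariate, without genes at the floor, and without any 1 of 6 arrays: HMACT saline replicate 3, HMACT methamphetamine replicates 2 and 3, LMACT saline replicates 4 and 6, and LMACT methamphetamine replicate 5. In the fit of all arrays all 6 members not at the floor on every array were lower in HMACT, with a median of -0.32. Adjusted over the list alone, 3 members passed and all were lower: Mobp (-0.80, SE 0.193), Cldn11 (-0.54, SE 0.186) and Mal (-0.38, SE 0.138), all genes of myelin. In the heat shock and oxidative stress list (adjusted p = 0.955), 2 passed higher and 3 lower when adjusted over the list alone. Dnajb1 (0.76, SE 0.178) and superoxide dismutase Sod1 (0.31, SE 0.0825) were higher, and catalase Cat (-0.18, SE 0.0518) and the glutathione synthesis gene Gclm (-0.39, SE 0.133) lower. The immediate early gene Dusp6 was lower (-0.49, SE 0.127) and so was the glucocorticoid-induced kinase gene Sgk1 (-0.50, SE 0.106). Among astrocyte markers S100b was higher (0.38, SE 0.129) and Gja1 lower (-0.45, SE 0.158), and among cortical markers Nrgn was higher (0.72, SE 0.233). Each of these passed when adjusted over its list alone and 0 passed over all genes. Of the 12 named members past in this way, 8 kept their direction in all 3 lots.

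The adjusted p-values of the other lists between the lines were 0.511 for immediate early genes, 0.806 for glucocorticoid responsive genes, 0.955 for striatal projection neuron genes and 0.955 for circadian clock genes. They were 0.823 for glutamate and GABA synapse genes, 0.977 for monoamine genes, 0.823 for mitochondrial respiratory chain genes and 0.975 for astrocyte markers. Members with the smallest p that did not pass included Foxp1 (-0.72, SE 0.286), Ptpn5 (0.42, SE 0.219), Tef (0.41, SE 0.160), Clock (-0.64, SE 0.288), Grik1 (-0.15, SE 0.0530), Gabrb1 (-0.50, SE 0.204), Th (0.19, SE 0.127), Htr4 (-0.08, SE 0.0697) and Ndufb10 (0.82, SE 0.265). Without HMACT saline replicate 3 Ptpn5 was 0.27 and Th 0.11, and without LMACT saline replicate 4 Htr4 was -0.02. Csnk1e had a log2 difference of 0.34 (SE 0.188) at an adjusted p of 0.447, and 0.20 without LMACT methamphetamine replicate 5.

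After saline alone, Sgk1 (-0.73, SE 0.147), Pih1d1 (1.86, SE 0.333) and Slc15a2 (1.23, SE 0.235) had adjusted p-values of 0.135, and Csnk1e had a log2 difference of 0.39 (SE 0.259). These genes other than Csnk1e were named after their values were seen. With limma 0 genes passed, and 1256 had an unadjusted p under 0.05 against 412.55 expected by chance. Genes that vary together spread such counts widely, so the excess does not show a line effect. These groups also differed on the array axis, with a mean score of 16.1 for HMACT saline and -19.9 for LMACT saline. No list passed; with the array axis as a covariate, the oligodendrocyte markers and the glucocorticoid responsive genes did. Without HMACT saline replicate 3, Csnk1e had 0.24. Array weights gave 8 genes, and leaving out HMACT saline replicate 1, HMACT methamphetamine replicate 3 or LMACT saline replicate 1 gave 1 each and leaving out LMACT methamphetamine replicate 5 gave 2.

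After methamphetamine alone, the oligodendrocyte markers were lower in HMACT as a list, with all 6 members above the floor negative and a median of -0.55. The list's adjusted p was 0.0030, and the call was lost with an estimated correlation (adjusted p = 0.216), without HMACT methamphetamine replicate 5 and without LMACT methamphetamine replicate 4. No member passed when adjusted over the list alone; Mobp had -0.86 (SE 0.280) and Cldn11 -0.58 (SE 0.269). Over all genes 0 passed with limma and 354 had an unadjusted p under 0.05. Nudt19 (-2.25, SE 0.426) and Dkk3 (1.07, SE 0.190), named after their values were seen, had an adjusted p of 0.131. Csnk1e had a log2 difference of 0.30 (SE 0.272), nearly all of which rests on LMACT methamphetamine replicate 5: without that array it was 0.01. Array weights gave 153 genes, leaving out HMACT saline replicate 3 gave 3, and leaving out HMACT methamphetamine replicate 3, LMACT saline replicate 2 or LMACT saline replicate 3 gave 1 each.

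Markers of other cell types were not called in the mean effect of methamphetamine. Adjusted p-values were 0.955 for astrocyte, 0.641 for oligodendrocyte, 0.913 for microglia, 0.641 for endothelial, 0.955 for choroid plexus and ependymal and 0.823 for interneuron markers. They were 0.127 for cortical and pallial, 0.813 for septal, hypothalamic and thalamic, and 0.955 for red blood cell markers. The cortical and pallial markers passed without any 1 of 3 arrays: HMACT saline replicate 4, LMACT saline replicate 2 and LMACT methamphetamine replicate 5. Members with small p-values and values above the floor had log2 differences of -0.10 for S100b (SE 0.129), -0.13 for Mal (SE 0.138), -0.25 for Tyrobp (SE 0.273), 0.37 for Vwf (SE 0.290), 0.42 for Pvalb (SE 0.318) and -0.31 for Nrgn (SE 0.233). Single arrays carried much of these: without HMACT saline replicate 3 Nrgn was -0.13 and Pvalb 0.23, without LMACT methamphetamine replicate 4 Vwf was 0.21, without LMACT methamphetamine replicate 5 S100b was -0.03 and Mal -0.03, and without HMACT methamphetamine replicate 6 Tyrobp was -0.16. Between the lines, the adjusted p was 0.823 for microglia, 0.955 for endothelial, 0.955 for choroid plexus and ependymal, 0.808 for interneuron, 0.641 for cortical and pallial, 0.927 for septal, hypothalamic and thalamic, and 0.511 for red blood cell markers. C1qb (1.03, SE 0.471), Pvalb (-0.87, SE 0.318), Tek (-0.16, SE 0.0644) and Hbb-b2 (0.39, SE 0.233) had the smallest p in their lists and did not pass.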

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

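The tests of the array axis, and those of RNA integrity, chip lot and cell type for the arrays that stand apart, were chosen after the results were seen, and so were the splits that keep same-numbered pools together; the others named here were set beforehand. Dixon's test was applied to 164 groups of values, and chance flags about 1 in 20. It picked out 16.

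LMACT methamphetamine replicate 4 had an array axis score of 56.5, against -20.6 to -12.2 for the others of its group. LMACT methamphetamine replicate 5 had a 3' minus 5' control difference of 4.57 (others 2.26 to 2.62), and HMACT saline replicate 3 one of 1.07, below the others of its group. The mean age of the pool was 127.5 days for LMACT saline replicate 6 and 114.75 days for LMACT methamphetamine replicate 6, where the others of these groups were 60 to 72.75 days. In log2 expression, Coa3 was 7.71 in LMACT methamphetamine replicate 2, Cfl1 12.2 in HMACT saline replicate 3 and 10.40 in HMACT methamphetamine replicate 5, and Dkk3 6.88 in LMACT saline replicate 2. Egr2 was 9.16 and Dnajb1 5.52 in LMACT saline replicate 5, Dusp1 10.20 in HMACT methamphetamine replicate 3 and Ddit4 7.26 in HMACT saline replicate 1. Sgk1 was 9.45 and Csnk1e 6.92 in LMACT methamphetamine replicate 5, and Cat was 2.75 in HMACT saline replicate 3. No named gene met the criteria for a difference between the lines' responses.

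The labels place the arrays that stand apart in 3 lots: 2 of the 15 arrays of the largest, 1 of 3 in another, and the only array of the fourth. Most arrays of the first of these lots do not stand apart, nor do the other arrays of the next, which argues against those lots as the whole cause. For the single array of the fourth lot this stays open; the test counted 2 lots, taking the fourth lot's number as a typing error for the third's, which is a guess. Degraded RNA would raise the 3' minus 5' difference, and their median was 2.07 against 2.54 for the rest. HMACT saline replicate 3 (1.07), HMACT methamphetamine replicate 3 (2.00) and LMACT methamphetamine replicate 4 (2.26) had the lowest difference of their groups. HMACT saline replicate 5 (2.14) did not. Standing apart thus went with a low 3' minus 5' difference in part, and the source of this link was not tested. Replacement of tissue by another cell type would lower the genes of striatal projection neurons, but these had a median log2 difference of 0.49 (10 genes, quartiles -1.04 and 1.35) while 226 genes were lower by over 2. This test looked for a fall of over 2 log2 units, so it cannot exclude a smaller share of another cell type. It replaced an earlier one after the earlier result was seen. The earlier one set marker lists against 10000 random lists: the microglia markers lay above all of them (C1qa 2.58, C1qb 2.40, but Ctss -0.94), and the other lists did not stand out. What produced the axis, sequence composition of the probes included, stays open.

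The lower chaperone genes after methamphetamine (Hspa1b, Hspa1a and Dnajb1) had a mean log2 difference of -1.10 (SE 0.179). It was -1.13 (SE 0.163) with the array axis as a covariate and -1.07 (SE 0.186) with the 3' minus 5' difference, so these tests argue against either as the whole cause. It was negative in 3 of 3 lots (-1.08, -1.12 and -1.20), with the fourth counted with the third. Methamphetamine, which the design names, may account for it, as a hypothesis found and tested on the same data; handling and the time of day were not tested.

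The 16 genes called between the lines were compared with those of pools under 100 days (6 of HMACT and 9 of LMACT). The median relative size of the differences was 0.911 there, all 16 kept their direction and exceeded 2 SE, and the median size fell from 0.87 to 0.77 while the median SE went from 0.159 to 0.164; 0 of the 16 were called with these fewer arrays. With mean age as a covariate 1 of the 16 was called, at a median relative size of 0.916 and a median SE of 0.180. With the array axis as a covariate the median relative size was 0.853. The pools under 100 days cannot separate age from line. Every HMACT pool there was older (77.25 to 88 days) than every LMACT pool (60 to 72.75 days). All 16 genes were also chosen on a fit that includes these arrays. The sizes kept with the covariates argue only against a linear trend with age, or the axis, as the whole cause. A strain variant under the probes stays open: only Prom1 had a second probe set above the floor, with 0.543 of the difference. A difference between the selected lines may be the cause, as a hypothesis.

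Splits of the same arrays were counted, 100 per comparison with the real grouping included. For the mean line difference the real grouping gave 16 genes and the highest other split gave 1. The real grouping was the only 1 of 100 with as many. These splits take the arrays as independent, so they cannot exclude chance if same-numbered pools vary together. Same-numbered pools of a line share a lot and are close in age, so 100 splits of the 12 numbered sets that kept them together were also counted. There 2 of 100 gave as many, the real one included, but the highest other called 1091 genes. It placed all 4 arrays that stand apart and 10 of the 12 HMACT arrays on 1 side, which points to a structure of the samples. For the mean effect of methamphetamine (2 genes) the highest other split also gave 2, and 3 of 100, the real one included, gave as many. For the effect in HMACT (1 gene), 4 of 100 gave as many, the real one included, but the highest other split called 1003 genes; it placed all 3 arrays that stand apart on 1 side, which points to a structure of the samples. For the effect in LMACT the real count was 0 and all 100 splits gave as many, the highest other 8; for the interaction 0, 100 and 1; after saline 0, 100 and 1. After methamphetamine the real count was 0, and all 100 gave as many, with a highest of 452 when both arrays that stand apart lay on 1 side. A count of 0 is reached by every split, so these 4 say nothing about chance.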

How the results depend on the processing

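The settings that left out genes at the floor or arrays that stand apart, or used the array axis as a covariate, were chosen after seeing the data. Where a count changed, the cause was not tested, unless fewer arrays or genes were used. Counts of genes for the effects in HMACT, LMACT and their mean, and for the line difference after saline, after methamphetamine and as a mean, were 1, 0, 2, 0, 0 and 16; the interaction gave 0 genes in every setting run. Array weights gave 2, 25, 6, 8, 153 and 677. Without the dimmest 40% of genes the first 3 were 2, 1 and 4, and the mean line difference 29. The 15 arrays of the largest lot alone gave 0 for HMACT, 0 for the mean effect and 1 for the mean line difference, and lot as a covariate without the array of the fourth lot gave 30. Mean age as a covariate gave 1 for the mean line difference; pools under 100 days gave 1 for LMACT, 1 for the mean effect and 1 for the mean line difference. The random block of line and number (correlation 0.216) gave 2, 1 and 4, and kept 4 of the 16 genes of the mean line difference. Quantile normalization gave 1 after methamphetamine, and all probe sets 1 after saline. Fits of only the groups compared gave 0 for HMACT, 1 for LMACT and 1 after saline. Without genes at the floor LMACT had 1. Without the arrays that stand apart the counts were 3, 1, 5, 1, 3 and 46, and with the axis as a covariate 2, 1 and 7, then 14 after methamphetamine and 37 for the mean line difference. Of its 16 genes, 16 kept their direction in all these settings run gene by gene, and 13 were called without the arrays that stand apart.

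Leaving out each array gave 1 to 2 genes for HMACT, 0 to 2 for LMACT, 2 to 5 for the mean effect, 0 to 2 after saline, 0 to 3 after methamphetamine and 9 to 76 for the mean line difference. Of 10 list calls, 3 held with an estimated correlation and 1 with fry, that of the immediate early genes in the mean effect of methamphetamine. Other settings gave 9 to 13, and leaving out an array gave 8 to 12. The correlation of the responses in the lines reversed to 0.0837 with the array axis as a covariate; leaving out an array gave -0.650 to -0.0680. The replicate block gave 0 genes for HMACT, 2 for the mean effect and 15 for the mean line difference. Same-numbered pools of a line share a lot (with the fourth counted with the third) and are close in age. Of 11 same-numbered pairs, 8 correlated over 0.1 (range -0.618 to 0.876), and in 5 the saline array correlated best with its own number. These pools thus varied together in part, though not in every pair. Line difference p-values that take the arrays as independent may therefore be too small. For named genes outside the leave-one-out settings, 1544 results kept their side of the threshold, 69 lost it, 27 gained it and 25 moved. Most of the 1544 belong to genes that were not called and stayed so. The 69 come only from the few called genes, so these lost their calls more often than the totals show. Signal over the floor limits dim genes, 2089 of which had no value above it.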

Other observations

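The array axis and the genes at its ends were chosen after the result was seen, and so was its use as a covariate. The genes lowest on the 4 arrays that stand apart included Gnai3 (log2 difference -4.96), Zranb2 (-4.70), Stag2 (-4.26) and Dcx, a gene of young neurons (-3.86). The highest included Znhit2 (2.94), Vps72 (2.85), Mcrs1 (2.52), C1qa (2.58) and C1qb (2.40).

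Genes of selected lines that were fixed for different parental segments could lie side by side, so adjacent genes might differ together. Among 5303 genes ordered by the GRCm38.p6 annotation, 271 had an unadjusted p under 0.01 between the lines. They formed 18 adjacent pairs, against a median of 14 and a central range of 7 to 21 in 10000 random orders (permutation p = 0.142), and 14 of the 18 pairs shared a direction. By the criterion set beforehand, a count within that range argues against linked segments; after the value was seen the reading was changed to open, because 18 lies above the median. No excess was detected. Blcap and Nnat, which overlap, formed 1 of these pairs. With the array axis as a covariate, an alternative chosen after seeing the data, there were 14 pairs against a median of 10 (permutation p = 0.159).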
